A study of Mus musculus with 6 samples.

How the data were processed

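Lineage-negative, cKit-positive, Sca1-negative bone marrow cells of polyIC-treated mice were profiled on Affymetrix mouse expression arrays. Per the labels' protocols, 5 ng of total RNA per sample was amplified and labelled by an Ovation kit. The deposited table held 1 intensity per probe set and array, which the authors made with RMA (background correction, quantile normalization and summary of probes), per the submitters' processing notes; the version is not given in the sources used here. The values were on a linear scale, from about 5.13 to 24678.6, and log2 was taken here. The 6 arrays had nearly the same distribution of intensities. RMA forces this, so a change in the total amount of RNA per cell would not be seen. Scanner files were not analysed here, so no measured background or detection call lies behind the values.

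The table held 45101 probe sets, of which 64 were array controls. By the platform annotation, 34958 probe sets had 1 gene, 932 had several and 9211 had none listed. Only probe sets with 1 gene were named. Of these, 34754 matched a mouse RefSeq gene table (GRCm38.p6) by gene identifier and no symbol needed an update. A probe set was tested where it lay above its array's 40th percentile on at least 3 of 6 arrays, which left 27424 probe sets and 12837 genes. A gene was read by its probe set of highest mean over the 6 arrays. For 6054 genes with several probe sets, none had probe sets called in opposite directions, but the size of a change could differ between them.

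Groups were taken from the labels, with 3 ICN2-negative and 3 ICN2-positive arrays. Every difference is ICN2-positive minus ICN2-negative. The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 intensity, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05, and every adjusted p of a gene comes from it. Errors given beside a difference are the standard errors of this fit. The 24 gene lists were fixed before the data were examined, together with the test, the groups and the rule for named genes. They were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists, with an estimated correlation and with fry as alternatives.

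Where all 3 arrays of a single group lay below their 40th percentile, the fold was computed against that percentile and is given as "at least". This choice was made after the values were seen. The percentile is the filter's limit, not a measured background, so these folds are lower bounds under that limit. Where only 1 or 2 of the 3 arrays lay below it the fitted difference is given, as for Xist, Nkx1-2 and Tctex1d1 (1 of 3 above it in the lower group) and Hey1, Il4, Nrp1 and Ptpro (2 of 3 above it).

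Named genes were Notch2, the sex-linked list and up to 4 members of each list with the smallest p. The 10 largest rises and 10 largest falls among separated genes past the threshold were also named, leaving out the sex-linked list and clone names. Dtx4, Notch1, Il2ra, Dtx1 and Hey2, the T cell receptor genes and Rosa26 were named after their values were seen, and the neighbours of Rosa26 were taken by position.

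The fit was tested on simulated data with 12837 genes, 200 seeded changes and 5 simulations at the spread of these arrays. It recovered 64% of changes of 1 on the log2 scale and 87% of changes of 2, and 3.70% of its calls were false. The simulated errors were independent between genes and of equal spread on all arrays, which does not hold for the real arrays. These rates therefore do not carry over to the calls made here. Alternatives covered the filter, normalization, the variance model, array weights, probe set choice, the replicate number as a term, each array left out, thresholds and the list tests. Intervals over genes are 95% bootstrap intervals from 10000 resamples. They cover the choice of list genes, not the spread between animals.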

Results

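Gene expression was measured on 6 arrays in sorted mouse bone marrow cells that lacked lineage markers and Sca1 and carried cKit, a population termed myeloerythroid progenitors in the labels. The mice were 6 weeks old and had received 3 injections of polyIC at 20 mcg per g of body weight, the last of them 1 week before the cells were taken. PolyIC induces interferon, which switches on the Mx1-cre recombinase. In ICN2-positive mice the recombinase removes a stop cassette in front of a Rosa26 transgene for ICN2, the intracellular domain of Notch2, which acts as a constantly active form of the receptor. Littermates with Mx1-cre but without the transgene were the ICN2-negative group. Each group had 3 arrays. All ICN2-negative samples came from females and all ICN2-positive samples from males, so genotype and sex cannot be told apart in any comparison between the groups. The labels do not state that the replicates of a group were separate animals, and p-values then measure only the spread between these samples, which may be technical. The number of arrays limits the precision. Median log2 intensity lay between 6.05 and 6.09 on the 6 arrays. ICN2-positive replicate 1 stood apart from its group, with a correlation across probe sets of 0.966 and 0.974 to ICN2-positive replicates 2 and 3, which correlated with each other at 0.991. Correlations among the ICN2-negative arrays were 0.989 to 0.991.

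The comparison of the genotypes asked how active Notch2 signalling changes gene expression in myeloerythroid progenitors. Among the largest rises in ICN2-positive cells, the mast cell proteases Mcpt1 and Mcpt2 were at least 21.9-fold and at least 31.5-fold higher (adjusted p = 0.00963 and 0.0025), and Mcpt4 at least 7.05-fold higher (adjusted p = 0.0183). The cytotoxic granule proteases Gzma and Gzmb rose by 5.94 ± 0.65 and 5.07 ± 0.28 on the log2 scale (difference ± SE, n = 3 per group), which is 61.3-fold and 33.5-fold. The metalloprotease gene Adamdec1 was at least 22.1-fold higher and the basement membrane gene Nid1 at least 18.3-fold higher. The other Nid1 probe set differed by 0.85 on the log2 scale and was not called. Col18a1, a basement membrane collagen, rose by 5.23 ± 0.19, Hs6st2, a heparan sulfate sulfotransferase, by 5.40 ± 0.18, and the homeobox gene Nkx1-2 by 6.10 ± 0.53, with 1 of 3 ICN2-negative arrays above the 40th percentile of intensity. The 3 Nkx1-2 probe sets ranged from 0.17 to 6.10, with 2 of them called. Hs6st2 lies on the X chromosome, and its other probe set rose by 2.03 and was also called. Among the largest falls, Flt3, a cytokine receptor of early lymphoid and dendritic progenitors, fell by 3.71 ± 0.29 (13.1-fold), and Dntt, the terminal transferase of lymphoid progenitors, fell by 4.39 ± 0.82 (21.0-fold, adjusted p = 0.0481). The Dntt call was lost on leaving out any single array (adjusted p = 0.0532 to 0.17). Slpi, a protease inhibitor of myeloid cells, fell by 4.07 ± 0.49, the semaphorin co-receptor gene Nrp1 fell by 4.06 ± 0.42 and Il6st, the shared receptor chain of the interleukin 6 family, fell by 3.40 ± 0.45. The 3 Il6st probe sets ranged from -3.40 to -0.23, with 2 of them called. The other large falls were in Tctex1d1 (26.2-fold, with 1 of 3 ICN2-positive arrays above the 40th percentile), Ptpro (11.8-fold), Mgst2 (9.86-fold), Ahnak (9.75-fold) and Abca9 (at least 8.71-fold). The other Abca9 probe set differed by -1.42 on the log2 scale and was not called.

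In all, 560 of 12837 genes tested (4.36%) passed an adjusted p of 0.05 in limma, 332 of them higher and 228 lower in ICN2-positive cells. Among these, 150 genes were at least 2-fold higher and 140 at least 2-fold lower. All 560 had 3 values in one group above the 3 in the other. Over all genes tested, 37.5% were separated in this way, against 10% by chance. At the level of probe sets, 728 of 27424 passed, 457 higher and 271 lower. The number of calls depended on single arrays. It was 99 without ICN2-negative replicate 2, 100 without ICN2-negative replicate 3 and 272 without ICN2-negative replicate 1. It was 141 without ICN2-positive replicate 3, 334 without ICN2-positive replicate 2 and 768 without ICN2-positive replicate 1. The signs of the 560 genes could not change in these fits, because all 560 were separated. Of the 20 genes named for the largest changes, 14 missed the threshold on leaving out at least 1 array, and Nkx1-2, Mcpt2, Hs6st2, Col18a1, Gzmb and Flt3 passed it in every such fit.

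Of 14 measured Notch target genes, 7 rose, none fell and 7 did not pass the test. Adjusted over the list alone, 7 were higher and 2 lower (7 to 8 and 0 to 2 with 1 array left out). Hey1, a transcriptional repressor induced by Notch, went from 5.79 ± 0.50 to 9.07 ± 0.23 (log2 intensity, mean ± SD, n = 3), a 9.67-fold rise (adjusted p = 0.00723). The repressor gene Hes1 rose 3.54-fold (adjusted p = 0.00723), and Nrarp, a feedback inhibitor of Notch, rose 4.45-fold (adjusted p = 0.00907). Il2ra, the interleukin 2 receptor alpha chain, was at least 5.33-fold higher, the receptor gene Notch3 at least 3.35-fold, the ubiquitin ligase gene Dtx1 at least 2.10-fold and Hey2 at least 1.71-fold. Dtx4 differed by -2.39 and Notch1 by -0.81 on the log2 scale without passing the test. The median change of the list was 1.01 (log2), with an adjusted p of 0.0323 in camera, which sets a list against all other genes. The adjusted p was 0.81 with an estimated correlation and 0.0196 in fry, which tests whether members move one way. The number of genes that rose was 4 without ICN2-negative replicate 2, 3 without ICN2-negative replicate 3 (Nrarp then at an adjusted p of 0.0562) and 5 to 7 without any other single array, with 1 gene lower without ICN2-positive replicate 1. The list call was also lost without ICN2-positive replicate 2 (adjusted p = 0.0801) and with a stricter filter on dim probe sets, where the median was 0.068. With no filter the median was 0.36 (adjusted p = 0.0112). None of 22 measured Notch pathway components passed at an adjusted p of 0.05 in limma, and adjusted over the list alone 2 were higher and 1 lower (none higher and 0 to 1 lower with 1 array left out). Without ICN2-positive replicate 1, 1 component was lower over all genes. The component with the smallest p was Psen2, a subunit of gamma-secretase, at 0.43 ± 0.09 (adjusted p = 0.0645).

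**Figure D1:**
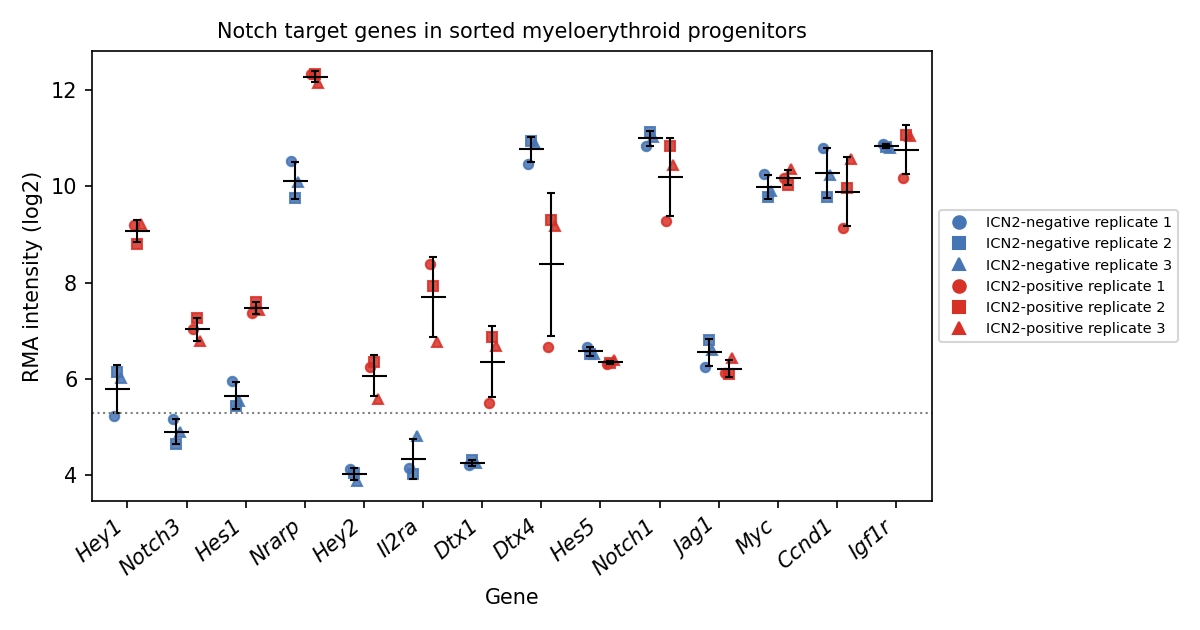
Log2 RMA intensity (vertical axis) of the 14 measured Notch target genes (horizontal axis) on each array, with ICN2-negative arrays in blue and ICN2-positive arrays in red. Black bars are group means with SD (n = 3), and the dotted line is the mean over arrays of the 40th percentile of intensity. Hey1 goes from a mean of 5.79 to 9.07.

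The Notch2 gene itself was read by 2 probe sets that differed. The brighter one changed by 0.07 ± 0.07 (log2, gene level adjusted p = 0.507). The dimmer one rose from 6.54 to 7.39 (adjusted p = 0.0158 over probe sets). Whether either probe set covers the part of Notch2 held in the transgene was not determined here, so they check the genotype labels only in part.

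All 17 measured genes of granulocyte-monocyte progenitors had lower means in ICN2-positive cells, and none passed the test for single genes, also when adjusted over the list alone. The median change was -1.59 (log2, adjusted p = 1.04e-04 in camera, adjusted p = 0.81 with an estimated correlation and 0.248 in fry). Csf3r, the receptor for granulocyte colony-stimulating factor, differed by -2.26 ± 0.49 (adjusted p = 0.0651). The transcription factor genes Gfi1 and Irf8 differed by -2.91 ± 0.85 (adjusted p = 0.109) and -3.15 ± 1.19 (adjusted p = 0.164). The arrays of the ICN2-positive group were unlike in this list: its median lay at -3.40 from the ICN2-negative mean in ICN2-positive replicate 1, at -0.50 in replicate 2 and at -0.76 in replicate 3. The difference between 3' and 5' probe sets was also the highest of the 6 arrays in replicate 1 for 3 of 4 control transcripts, at 1.01 (log2) for beta-actin against at most 0.85 elsewhere. Without replicate 1 the median was -0.61, and in a count added after the values were seen 8 of the 17 genes passed, all lower, and 13 over the list alone. The adjusted p of the list in that fit was 1.64e-09 in camera and 0.639 with an estimated correlation. With array weights the median was -0.87.

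Genes of monocytes, macrophages and dendritic cells were lower as a list, with a median of -0.50 (log2, adjusted p = 2.96e-04 in camera, adjusted p = 0.81 with an estimated correlation and 0.0473 in fry). Of 22 measured, 2 fell, which were Flt3 and the adhesion molecule gene Vcam1 at -2.71 ± 0.45 (adjusted p = 0.038). The count was 11 lower adjusted over the list alone (1 without ICN2-negative replicate 2, 5 without ICN2-negative replicate 1 and 7 to 11 without any other single array), and 6 lower over all genes without ICN2-positive replicate 1. Vcam1 kept its call in that fit and lost it without any other single array (adjusted p = 0.059 to 0.145). The list median was -1.82 with a stricter filter and -0.29 without probe sets that may read several transcripts. Of 15 late neutrophil genes, Mmp8, a collagenase of neutrophil granules, fell at least 2.37-fold (adjusted p = 0.00758) and 14 did not pass. The late neutrophil median was -0.91 (adjusted p = 9.67e-04 in camera, adjusted p = 0.81 with an estimated correlation and 0.194 in fry), with 4 genes lower adjusted over the list alone (1 to 4 with 1 array left out). Without ICN2-positive replicate 1 the median was -0.53 and 3 genes were lower, and 2 were lower without ICN2-negative replicate 1.

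Of 13 measured B cell genes, Dntt fell and 12 did not pass, with a list median of -1.78 (adjusted p = 0.00931 in camera, adjusted p = 0.81 with an estimated correlation and 0.285 in fry). With 1 array left out this median was -2.54 to -1.09. The adaptor gene Blnk differed by -2.57 ± 0.61 (adjusted p = 0.0749), and 2 B cell genes were lower adjusted over the list alone (8 without ICN2-negative replicate 3 and 0 to 2 without any other single array). The ICN2-negative arrays themselves ranged from a B cell list median of 1.48 in replicate 1 to -1.30 in replicate 3, and the list call was lost without ICN2-positive replicate 1 (adjusted p = 0.0748) and with array weights (adjusted p = 0.0698). Without ICN2-positive replicate 1, 1 B cell gene was higher and 1 lower over all genes. None of 16 measured T cell genes passed, adjusted over all genes in limma or over the list alone, and their median was 0.72 (adjusted p = 0.095 in camera). The median was 0.45 to 0.82 with 1 array left out. Over the list alone, 3 were higher without ICN2-positive replicate 1 and 1 without ICN2-negative replicate 1. Without ICN2-positive replicate 1, 2 of them passed over all genes, both higher (Cd7 at 3.07, adjusted p = 0.042), and without ICN2-positive replicate 3, 8 were higher and 1 lower over the list alone. Of 8 NK cell genes, Gzma and Gzmb rose and the rest did not pass, with the same counts adjusted over the list alone and a median of 0.17 (adjusted p = 0.251 in camera). Nkg7, a granule gene of cytotoxic cells, differed by -0.30 ± 0.15. Without ICN2-positive replicate 1, camera called the T cell list (adjusted p = 0.0239) and the NK cell list (adjusted p = 0.0216) higher, with an adjusted p of 0.639 for each with an estimated correlation. It also called the T cell list without ICN2-positive replicate 3 (adjusted p = 0.00485, and adjusted p = 0.84 with an estimated correlation). The NK cell median was -0.07 without ICN2-positive replicate 2, and Gzma lost its call without ICN2-negative replicates 2 or 3 or ICN2-positive replicate 3 (adjusted p = 0.0592 to 0.0757).

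**Figure D2:**
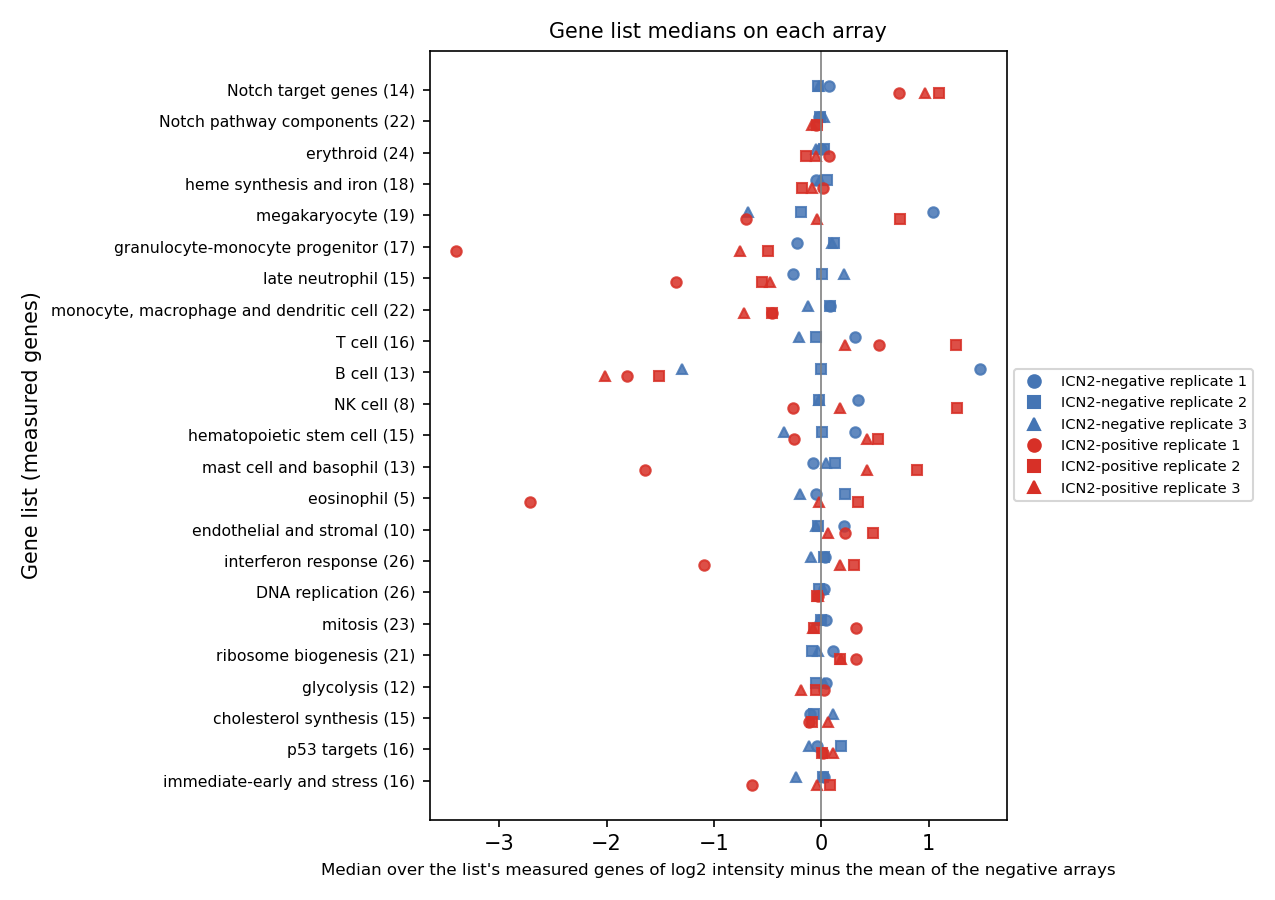
Median over each list's measured genes (number in parentheses) of the log2 intensity minus the mean of the 3 ICN2-negative arrays (horizontal axis), 1 point per array, with ICN2-negative arrays in blue and ICN2-positive arrays in red. ICN2-positive replicate 1 lies at -3.40 in the granulocyte-monocyte progenitor list and at -2.71 in the eosinophil list.

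Of 13 measured mast cell and basophil genes, 2 rose and 11 did not pass, with the same counts adjusted over the list alone. Besides Mcpt4, the cytokine gene Il4 rose from 5.31 ± 0.19 to 8.23 ± 0.20 (7.59-fold, adjusted p = 0.00178). The mast cell chymase gene Cma1 differed by 0.82 ± 0.27 (adjusted p = 0.129). The list's median was -0.03 while its mean was 0.33 and camera's direction was up (adjusted p = 0.424), so the signs differ. Its median lay at -1.64 in ICN2-positive replicate 1, at 0.89 in replicate 2 and at 0.43 in replicate 3, and without replicate 1 the median was 0.74 (adjusted p = 0.00951 in camera, adjusted p = 0.639 with an estimated correlation). The call of Mcpt4 was lost without any single ICN2-negative array (adjusted p = 0.0549 to 0.0934). None of 5 eosinophil genes passed in limma, while 1 was higher when adjusted over the list alone (none without any single array but ICN2-positive replicate 1), with a median of -0.84 (adjusted p = 0.668). Prg2, the eosinophil major basic protein gene, differed by -0.84 ± 0.80, and by 0.10 without ICN2-positive replicate 1, where Alox15, a lipoxygenase, passed over all genes (2.78, adjusted p = 0.035).

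**Figure D3:**
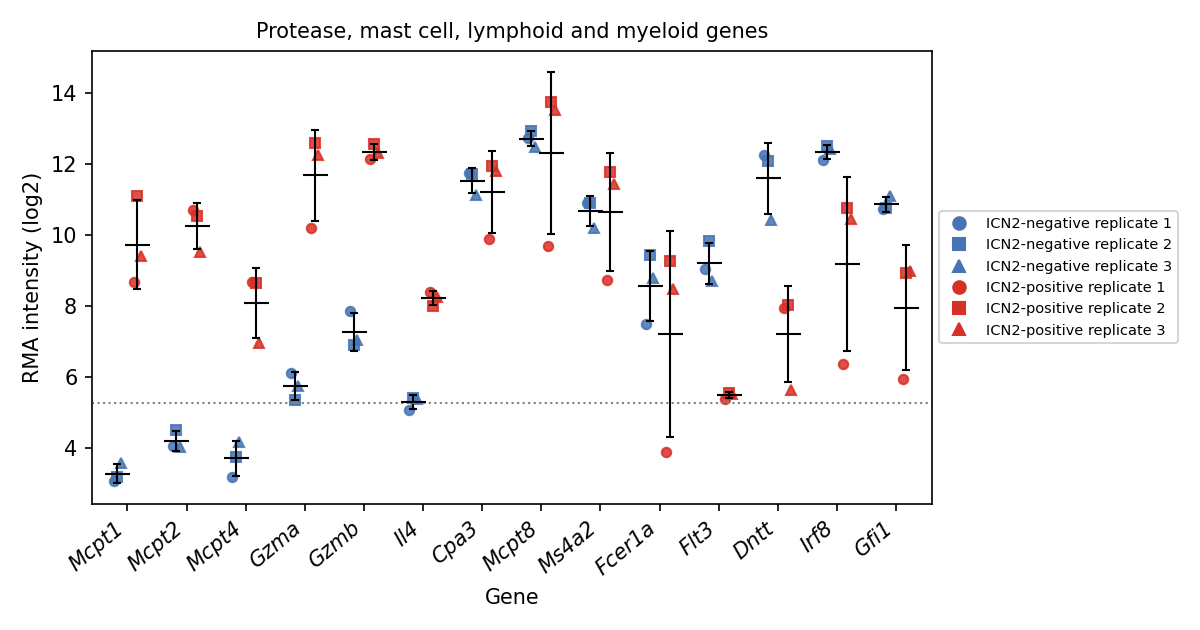
Log2 RMA intensity (vertical axis) of 14 protease, mast cell, lymphoid and myeloid genes (horizontal axis) on each array, with ICN2-negative arrays in blue and ICN2-positive arrays in red. Black bars are group means with SD (n = 3), and the dotted line is the mean over arrays of the 40th percentile of intensity. Gzmb goes from a mean of 7.28 to 12.3 and Flt3 from 9.21 to 5.50, and the genes other than those named in the text were drawn after their values were seen.

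Of 24 measured erythroid genes, 4 fell and 20 did not pass. Trim10, needed for late erythroid maturation, fell by 1.60 ± 0.13 on the log2 scale (3.04-fold, adjusted p = 0.00718). The red cell membrane skeleton genes Epb42 and Sptb differed by -1.94 ± 0.27 (adjusted p = 0.0239) and -1.13 ± 0.12 (adjusted p = 0.0106), and Cldn13 fell by 0.53 ± 0.08. The other probe sets of Epb42 (-0.17) and Sptb (-0.03) were not called. In total 7 were lower adjusted over the list alone (4 to 8 with 1 array left out). With 1 array left out the number that fell was 1 to 5, and it was 1 (Trim10) without ICN2-negative replicate 2 or 3. Sptb was lost as the mean of its probe sets (-0.58, adjusted p = 0.0539) and without ICN2-negative replicate 2 (adjusted p = 0.0706) or 3 (adjusted p = 0.0679). Epb42 was lost without any single ICN2-negative array or ICN2-positive replicate 2 (adjusted p = 0.0609 to 0.108), and Cldn13 without any single array but ICN2-positive replicate 1 (adjusted p = 0.061 to 0.127). The list's median was -0.16 (adjusted p = 0.0387 in camera, adjusted p = 0.81 with an estimated correlation and 0.194 in fry). The list call was lost without ICN2-negative replicate 1 (adjusted p = 0.0587), ICN2-negative replicate 2 (adjusted p = 0.0874) or ICN2-positive replicate 2 (adjusted p = 0.314). Of 18 genes for heme synthesis and iron, Slc25a37, the mitochondrial iron importer, fell by 1.03 ± 0.19 (adjusted p = 0.0484) and 17 did not pass. This call was lost with no filter (adjusted p = 0.0558), median centring (adjusted p = 0.0523), robust eBayes (adjusted p = 0.0508) and the replicate number as a term (adjusted p = 0.0874). It was also lost without any single array but ICN2-positive replicate 1 (adjusted p = 0.0663 to 0.147). Adjusted over the list alone, 3 were lower (0 to 2 with 1 array left out), and the median was -0.09 (adjusted p = 0.103 in camera, and -0.14 with adjusted p = 0.017 without ICN2-positive replicate 1, where the adjusted p was 0.639 with an estimated correlation). Alas1, the first enzyme of heme synthesis in most tissues, differed by -1.79 ± 0.37 (adjusted p = 0.0601). None of 19 megakaryocyte genes passed in limma over all genes or over the list alone, with a median of -0.06 (adjusted p = 0.668 in camera). The platelet chemokine gene Pf4 differed by -2.94 ± 1.00. The megakaryocyte median lay at 1.04 in ICN2-negative replicate 1, and without it the group difference was 0.50, with 1 gene higher over all genes (Rab27b at 1.47, adjusted p = 0.0266) and 3 over the list alone.

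None of 15 hematopoietic stem cell genes passed in limma over all genes or over the list alone, with a median of 0.24 (adjusted p = 0.392 in camera). Without ICN2-positive replicate 1, 3 of them passed, all higher, with 5 higher and 1 lower over the list alone, and camera called the list (median 0.48, adjusted p = 0.0411, and adjusted p = 0.639 with an estimated correlation). The transcription factor gene Mycn differed by 3.38 ± 0.79 (adjusted p = 0.0738) and the angiopoietin receptor gene Tek by 1.90 ± 0.58 (adjusted p = 0.115). The 3 Mycn probe sets ranged from -0.12 to 3.38, and none was called. Of 10 endothelial and stromal genes, none passed over all genes and 3 were higher adjusted over the list alone (median 0.33, adjusted p = 0.309 in camera). With 1 array left out this median was 0.14 to 0.43. The count of 3 was 0 without any single ICN2-negative array and 1 to 2 otherwise, while Pdgfrb passed over all genes without ICN2-positive replicate 1 (1.74, adjusted p = 0.00424) and Sparc without ICN2-positive replicate 2 (1.62, adjusted p = 0.0298). The interferon response list held 26 measured genes, of which Ifih1, a sensor of double-stranded RNA, rose by 0.60 ± 0.10 (adjusted p = 0.0377), a call lost without any single array but ICN2-positive replicate 1 (adjusted p = 0.0714 to 0.141). Over all genes, 2 were higher without ICN2-positive replicate 1, and Mx1 was lower without ICN2-positive replicate 2 (-1.28, adjusted p = 0.0333). Adjusted over the list alone, 1 was higher (0 to 2 higher and 0 to 1 lower with 1 array left out), and the list's median was -0.18 (adjusted p = 0.201 in camera). It lay at -1.10 in ICN2-positive replicate 1, and without that array the group difference was 0.29 (adjusted p = 0.118). Camera called the list lower without ICN2-positive replicate 2 (-0.38, adjusted p = 0.0204) and without ICN2-positive replicate 3 (-0.39, adjusted p = 0.0366), with an adjusted p of 0.903 and 0.84 with an estimated correlation.

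All 21 measured ribosome biogenesis genes had higher means in ICN2-positive cells, by a median of 0.20 (log2, adjusted p = 1.04e-04 in camera, adjusted p = 0.81 with an estimated correlation and 0.166 in fry). None passed over all genes, and 3 were higher adjusted over the list alone (9 without ICN2-negative replicate 1 and none without any other single array). Polr1a, the largest subunit of RNA polymerase I, differed by 0.63 ± 0.13 (adjusted p = 0.0617). Of 16 p53 targets, Perp, a desmosome and apoptosis gene, rose by 2.04 ± 0.24, Zmat3 rose by 0.74 ± 0.10 and Sesn1 fell by 0.73 ± 0.11, and 13 did not pass. Each of the 3 calls was lost on leaving out any of 4 single arrays (adjusted p = 0.05 to 0.123), and none of the 16 passed without ICN2-negative replicate 3 or ICN2-positive replicate 3. Sesn1 also missed the threshold without shared-suffix probe sets (adjusted p = 0.109) and as the mean of its probe sets (adjusted p = 0.056). Adjusted over the list alone, 6 were higher and 2 lower (2 to 4 higher and 2 lower with 1 array left out), with a list median of 0.01 (adjusted p = 0.574 in camera). No gene passed over all genes in the lists for DNA replication (26 measured, median -0.05, adjusted p = 0.195), mitosis (23 measured, median 0.03, adjusted p = 0.651), glycolysis (12 measured, median -0.04, adjusted p = 0.424), cholesterol synthesis (15 measured, median -0.08, adjusted p = 0.424) and immediate-early and stress genes (16 measured, median -0.05, adjusted p = 0.358). Adjusted over the list alone, 3 glycolysis genes were higher and 5 lower (0 to 2 and 0 to 5 with 1 array left out), and the other 4 of these lists held no call. Over all genes 1 glycolysis gene was lower without ICN2-positive replicate 1, and 1 immediate-early gene without ICN2-positive replicate 2.

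Camera called 7 of 24 lists, and none of these calls held with an estimated correlation. Other ways to split the 6 arrays into groups of 3 gave up to 15 called lists, and each of those splits still held part of the genotype difference. The same splits gave 0 changed genes each, against 560 for the genotypes. Groups of mixed genotype carry the genotype difference as spread within groups, so these counts of 0 are no baseline for chance.

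Genes on the sex chromosomes followed the sexes in the labels. Xist, the X inactivation transcript, fell by 6.30 ± 0.21 on the log2 scale in ICN2-positive samples, with 1 of 3 ICN2-positive arrays above the 40th percentile, and the Y-linked genes Eif2s3y, Kdm5d and Uty were at least 67.1-fold, at least 7.68-fold and at least 4.91-fold higher. Kdm6a, an X-linked gene that escapes inactivation, fell by 0.89 ± 0.11 (adjusted p = 0.0213, and 0.0513 to 0.1 without any single ICN2-negative array or ICN2-positive replicate 2), and Eif2s3x differed by -0.33 ± 0.08 (adjusted p = 0.0841). Of 8 measured genes in this list, 3 rose and 2 fell, and adjusted over the list alone 3 were higher and 3 lower. The list's median was -0.02 and its mean 1.18 (adjusted p = 0.574 in camera and 0.00566 in fry), with opposite signs. On the X chromosome 21 of 377 genes tested changed (5.57%), against 4.33% of autosomal genes. Fisher's exact test set X-linked genes against all others with a known chromosome, including 5 Y-linked genes (two-sided, p = 0.249). The X-linked count does not bound what sex contributes to autosomal genes, since no array of either genotype came from the other sex.

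The difference between 3' and 5' probe sets of 4 control transcripts, a measure of RNA length, was compared between the groups. For Gapdh the log2 difference between 3' and 5' was 0.64 ± 0.02 in ICN2-negative and 0.68 ± 0.04 in ICN2-positive samples (SD, n = 3, two-sided exact permutation p = 0.3). For beta-actin it was 0.81 ± 0.04 and 0.82 ± 0.16 (exact permutation p = 1.0). For the transferrin receptor it was 3.13 ± 0.21 and 2.90 ± 0.04 (exact permutation p = 0.3), and for pyruvate carboxylase 1.82 ± 0.13 and 1.67 ± 0.26 (exact permutation p = 0.5). ICN2-positive replicate 1 had the highest value of the 6 arrays for Gapdh (0.73, others up to 0.66), beta-actin (1.01, others up to 0.85) and pyruvate carboxylase (1.97, others up to 1.90), and not for the transferrin receptor (2.92, others up to 3.28). The smallest p this design allows is 0.1, so these tests could not pass the threshold.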

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

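Counts of list members with 1 array left out, and the estimated correlation in those fits, were added after the values were seen; the settings here were planned. The sign of the 560 changed genes could not change on leaving out or weighting arrays, because all 560 were separated. The variance models and the balanced replicate block leave the difference itself unchanged. With another filter, normalization or probe set choice, the genes tested kept their sign, except 1 gene under the mean of a gene's probe sets. This carries little weight for the filters, which leave the values themselves unchanged. Median centring could not change a sign, because array medians lay between 6.05 and 6.09 and the smallest called change was 1.25-fold. Between 476 and 646 genes changed with no filter, a stricter filter, quantile normalization, median centring, robust eBayes, probe sets without shared suffixes or mean probe sets. An intensity trend gave 847 genes (365 lower) and 1216 probe sets. Array weights gave 3262 genes (1746 higher, 1516 lower) and 3970 probe sets, with a weight of 0.238 for ICN2-positive replicate 1 and 5.72 for replicate 3. A minimum of 2-fold left 290 genes (150 higher, 140 lower) and 415 probe sets, by construction, and an adjusted p of 0.1 gave 1601 genes (899 higher, 702 lower) and 2376 probe sets. Leaving out 1 array gave 99 to 768 genes (68 to 373 higher, 28 to 395 lower) and 95 to 860 probe sets, with fewer samples in each fit. The counts were 99, 100 and 272 without ICN2-negative replicates 2, 3 and 1, and 768, 334 and 141 without ICN2-positive replicates 1, 2 and 3. With the replicate block, 340 genes changed (178 higher, 252 shared with the 560) and 268 probe sets. Among the named genes, the block ended the calls of Gzma (adjusted p = 0.0519), Mcpt4 (0.0602), Epb42 (0.0519), Cldn13 (0.0732), Slc25a37 (0.0874), Ifih1 (0.0527), Perp (0.054) and Kdm6a (0.057). Replicate numbers were not shown to pair the samples: same-number deviations correlated at 0.183, 0.101 and 0.0945, and not every array correlated best with its own number.

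The Notch target median of 1.01 lost its call with a stricter filter (0.068, adjusted p = 0.328), without shared-suffix probe sets (0.88, adjusted p = 0.101), with the replicate block (1.01, adjusted p = 0.119) and with an estimated correlation (1.01, adjusted p = 0.81). It was 0.36 with no filter (adjusted p = 0.0112), and 0.91 to 1.16 with 1 array left out. The erythroid median lost its call with quantile normalization (-0.15, adjusted p = 0.0533), array weights (-0.051), the replicate block (-0.16, adjusted p = 0.122), an estimated correlation and fry (-0.16, adjusted p = 0.194), and ranged from -0.18 to -0.038 with 1 array left out. The granulocyte-monocyte median of -1.59 lost its call with an estimated correlation and with fry (adjusted p = 0.248), and was -0.87 with array weights. Dntt missed the threshold with no filter (adjusted p = 0.0546), with robust eBayes (adjusted p = 0.0505) and without any single array. Calls among the other lists numbered 4 in the main setting, 8 without ICN2-positive replicate 1, 0 with an estimated correlation and 2 with fry. The direction of the list test or of the value, given here as medians, reversed for the megakaryocyte list (0.038 with array weights, -0.42 to 0.50 with 1 array left out), the eosinophil list (-0.28 with no filter, -0.045 with array weights, -1.37 to 0.10 with 1 array left out), the mast cell and basophil list (-0.26 with a stricter filter or without shared-suffix probe sets, -0.59 to 0.74), the interferon list (0.21 with array weights, -0.39 to 0.29), the mitosis list (-0.053 with array weights, -0.095 to 0.13), the cholesterol list (-0.15 to 0.034), the immediate-early list (-0.19 to 0.058), the NK cell list (-0.070 to 0.71), the p53 list (-0.017 to 0.11), the glycolysis list (-0.14 to 0.026), the sex-linked list (-0.054 to 0.038) and Prg2 (-1.37 to 0.10), the last ranges with 1 array left out. For the eosinophil list with no filter or array weights, only the direction in camera reversed, and the median kept its sign (-0.84 in the main setting). The same held for the mast cell and basophil list with a stricter filter or without shared-suffix probe sets (-0.03 in the main setting). The Notch2 gene passed the test as the mean of its probe sets (0.46, adjusted p = 0.0339), which takes in the dimmer probe set. For the rest the cause was not tested. With no measured background, signal over background could not limit the calls further.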

Other observations

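The T cell receptor list, the tests on the granulocyte-monocyte genes and those on admixed cells were chosen after the results were seen, while the splits of the arrays and the question of sex were set before. Rosa26 was chosen after its own value was seen, and the test on its neighbours was set before theirs were. Of 7 T cell receptor genes tested, 3 rose in ICN2-positive progenitors and 4 did not pass in limma, with a median change of 2.78 on the log2 scale. Tcra was at least 2.26-fold higher (adjusted p = 0.00309), Trbv13-2 rose 7.31-fold (adjusted p = 0.00328) and Trbv1 rose 6.85-fold (adjusted p = 0.0336). Trgv4, a gamma chain variable segment, differed by 3.90 ± 0.84 (adjusted p = 0.0644). The T cell list fixed beforehand held no gene past the threshold, and its member Cd3e, a signalling chain of the receptor, differed by 1.35 ± 0.42 (adjusted p = 0.116).

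The transcript of the Rosa26 locus, where the ICN2 transgene sits, rose by 0.97 ± 0.14 on the log2 scale (1.97-fold, adjusted p = 0.0264). The 4 nearest tested genes, Srgap3, Thumpd3, Setd5 and Mtmr14, had a median change of -0.043, from -0.24 to 0.20, and none passed in limma, which argues against a rise of the whole neighbourhood. Whether the probe set reads transcript from the transgene allele was not tested.

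The granulocyte-monocyte progenitor genes lay lowest in ICN2-positive replicate 1, and that array also had the highest 3' to 5' difference of the 6 for Gapdh (0.73, others up to 0.66), beta-actin (1.01, others up to 0.85) and pyruvate carboxylase (1.97, others up to 1.90), but not the transferrin receptor (2.92, others up to 3.28). Degraded RNA or poor amplification of that array stays open. The list median minus the erythroid list median there (-3.47, 95% bootstrap interval -4.05 to -2.86) decides nothing. The list was picked for its fall on that array, and the normalization removes an equal fall of all lists. The eosinophil (-2.71), mast cell (-1.64) and interferon (-1.10) lists also lay low there. The B cell list lay low on ICN2-positive replicates 1, 2 and 3 alike (-1.81, -1.51 and -2.01). Other lists lay above the ICN2-negative mean on replicate 1, among them the Notch target (0.72), T cell (0.54), mitosis (0.33) and ribosome biogenesis (0.32) lists. The granulocyte-monocyte genes also lay lower on replicates 2 and 3. The median there was -0.61 (-0.94 to -0.44), and 14 of 17 genes lay below all ICN2-negative arrays. In other lists this held for 0 of 21 ribosome biogenesis genes up to 14 of 22 genes of monocytes, macrophages and dendritic cells. The interval takes the genes as independent (estimated correlation 0.78 without replicate 1), and the list was picked after the results were seen. These values therefore only describe the arrays. A smaller share of granulocyte-monocyte cells with no other change would raise the genes of all other cell types alike. A first test of this, on the erythroid list, decided nothing (-0.11, interval -0.50 to 0.04). In a second, chosen once that result was known, the mast cell and basophil list lay 0.86 above the erythroid list on replicates 2 and 3 (0.31 to 1.34). It decides nothing either, because the mast cell and basophil list was chosen after the values were seen. On replicate 1 that list lay below the erythroid list (-1.64 against 0.07). A smaller share, a joint shift in several cell types, lower expression per cell, and sex all stay open.

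The mast cell protease genes Mcpt1, Mcpt2 and Mcpt4 were at least 21.9-fold, 31.5-fold and 7.05-fold higher. The granzyme genes Gzma and Gzmb rose by 5.94 and 5.07 on the log2 scale. Admixed connective tissue mast cells or basophils would bring their other transcripts, but the 4 other list markers of low baseline went different ways: Il4 rose by 2.92, while Cma1 (0.82), Tpsb2 (0.077) and Cd200r3 (-0.44) did not pass, for a median of 0.45. Admixture of other kinds of mast cells was not tested. For admixed NK or T cells, 25 low-baseline markers had a median change of 0.90, although the sort removed cells with lineage markers. These markers took in T cell receptor genes, added after their values were seen, so the median decides nothing. The 3 markers past the threshold, Tcra, Trbv13-2 and Trbv1, were all receptor genes. None of the markers fixed beforehand passed, with changes from -1.07 for Lef1 to 2.31 for Cd7 (Lat 1.53, Cd3g 1.52). Both sources therefore stay open. Of the other markers, only Il4 rose for mast cells or basophils. For NK or T cells only receptor genes rose, which were added after their values were seen. Il4, Trbv13-2 and Trbv1 rose less far than Mcpt1, Mcpt2, Gzma and Gzmb. Mcpt4 and Tcra have only lower bounds, so they cannot be ranked. Expression of these genes in the progenitors themselves under ICN2 is a further candidate explanation, and sex, confounded with genotype, is untested.

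Of the changed genes with a known chromosome, 95.7% were autosomal, and for these genotype and sex cannot be told apart because each group held animals of 1 sex. The 6 arrays make 10 splits into groups of 3, too few for a share under 0.05. The genotype split was the 1 split with as many as 560 changed genes, and the highest of the others gave 0. For probe sets it was again 1 split, with 728 against 0. The other splits mix the genotypes, which adds their difference to the spread within groups, so these counts of 0 are no baseline for chance. For lists called by camera, 9 of the 10 splits gave as many as the genotypes (7 lists, highest other 15), and the other splits each still held part of the genotype difference.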
